A study of Mus musculus with 884 samples.

How the data were processed

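Single cells were sorted by DNA content from G1 and from several parts of S phase, amplified with SeqPlex and sequenced as 80-bp single reads, per the labels' protocols. Per the submitters' processing notes, cutadapt, BWA 0.7.10-r789 and Picard were used with the mm9 build; their order and settings were not given in the sources used here. Per the file headers, the authors corrected each cell for mappability with 1 of 14 merged G1 controls and turned it into calls per 80 kb bin of chromosomes 1 to 19, coded 1 for replicated, -1 for not replicated and 0 for no data. The deposited haplotype-resolved tables hold the same calls for chromosome X in 400 kb windows at d0, d2 and d7. The deposited replication score is a fraction, the share of replicated autosomal bins; recomputed here from the calls as a percentage, it differed from the deposited score by at most 5.00e-08 points. Read depth was not used here, and the number of bins called per cell stands in for it: at least 26813 in every window cell. The calls themselves fix much of the resolution, since smoothing and thresholds were set by the authors before deposit.

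Groups were taken from the titles. For 7 G1 cells the title named another day than the other labels, and they were kept out of every group. The cell line, the day and the sorting gate were the only labels that grouped cells; no culture or animal was named, so each day and the EpiSCs counted as 1 sample each, no test was run and cells were never used as replicates. Of the 59 d0 and 101 d7 window cells, 50 and 35 had been deposited in a previous series, some with further reads added.

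Per bin and group, the share of window cells called replicated was taken over cells with a call, for bins called in at least 50% of the group's window cells. Groups were compared by a fixed size rule, a difference of 0.3 or more, and runs of at least 5 adjacent bins formed a region of 400 kb or more. Named regions were the 8 with the largest mean difference in each direction from d0 to d7, the 4 in each direction for d0 to EpiSC and EpiSC to d7, and the 4 chromosome X windows with the largest and the 4 with the smallest difference between active and inactive X at d7, among windows called in at least 80% of cells, adjacent windows counting as 1. Regions were chosen and measured on the same cells. For a region, a cell counted as replicated when more than 50% of its called bins were. Coordinates are those of the files (mm9), written 1-based. The number of bins that counting error alone would move was simulated 20 times from the pooled share of both groups. The per-bin span was a logistic fit of the call on the cell's score, with 1% of calls taken as wrong, over S-phase cells with scores from 5 to 95%; bins with a midpoint of 10 to 90% were kept, and classed as early under 40% and late above 60%. Score matching took, for each cell of a group, the unused d0 or d7 cell closest in score.

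The steps were tested on simulated data before use. With d0 shares and 200 bins changed between d0 and d7, the size rule found 49 of 50 bins changed by 0.4, 50 of 50 changed by 0.5, 27 of 50 changed by exactly 0.3 and 4 of 50 changed by 0.2; 2 of 29488 unchanged bins compared passed. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures in matplotlib 3.10.9.

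The size rule, the window, the named-region rule and most alternatives were set before the data were examined. Alternatives covered the window, the measure (the logistic midpoint), the threshold, the filter on bins, the origin and number of cells, the minimum length and the type of correlation. Matching in score, leaving out 7 window cells whose calls ranked the bins of the mean profile with an area under the curve below 0.8, and leaving out the cells that the authors' own filters had marked were added after seeing the data. Gene lists planned for the d0-to-d7 comparison were not analysed here, because the gene table at hand is of another build (GRCm38.p6) than the files and no gene could be placed on a bin; for the same reason regions are named by position only. Chromosome X at 80 kb was not used here.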

Results

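DNA replication state was measured in 884 single mouse cells with single-cell Repli-seq, in which a cell is sorted from a chosen part of S phase, its genome is amplified and sequenced, and every stretch of the genome is called replicated or not yet replicated. The cells were CBMS1 female embryonic stem cells, a hybrid of the CBA and MsM strains grown in 2i/LIF (d0), the same line at d2, d3, d4, d5, d6 and d7 of a differentiation through epiblast-like cells and floating aggregates towards neurectoderm, and epiblast stem cells (EpiSCs). The autosomes 1 to 19 were covered by 30890 bins of 80 kb, of which a median of 29672 were called per cell (range 4355 to 29874). Labels placed 877 cells in a group, 805 in S phase and 72 in G1.

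The replication score of a cell is the percentage of its called bins that were replicated. It had a median of 0.157% in the G1 cells, with a maximum of 10.6%. Timing was compared in the 293 S-phase cells labelled with a score of 40 to 70%, in which early-replicating bins are mostly replicated and late ones mostly not. These window cells numbered 59 at d0, 35 at d2, 13 at d3, 18 at d4, 20 at d5, 21 at d6, 101 at d7 and 26 for EpiSCs. Their mean score was 56.3% ± 7.94 (SD over cells) at d0, 52.3% ± 7.90 at d2, 53.7% ± 10.1 at d3, 53.4% ± 8.06 at d4, 55.6% ± 8.55 at d5, 54.5% ± 8.50 at d6, 56.4% ± 8.34 at d7 and 57.1% ± 8.69 in EpiSCs. No label named separate cultures, so each group counted as 1 biological sample. No test was run between groups, and intervals given for numbers of cells are exact Clopper-Pearson 95% intervals that cover counting error only.

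Between d0 and d7, replication timing moved in both directions. The window cells of both days had nearly the same mean score (56.3% and 56.4%). Gains and losses in share must therefore nearly cancel over all bins, so the similar totals below follow largely from the window. A bin counted as changed when the share of window cells in which it was replicated differed by 0.3 or more. Of 29688 autosomal bins, 2300 (7.75%, 184 Mb) replicated earlier at d7 and 2290 (7.71%, 183 Mb) replicated later. Later-to-earlier bins were replicated in 25.1% of d0 cells and 70.5% of d7 cells on average, and earlier-to-later bins in 77.7% and 30.3%. Counting error alone would have put 0.7 and 0.8 bins past this difference. Measured instead as a shift of at least 30 points in the score at which a bin replicates, over all of S phase, 506 bins moved earlier and 791 later. Most changed bins lay in long runs: 190 later-to-earlier regions of at least 400 kb held 1967 bins, and 181 earlier-to-later regions held 1824 bins, with median lengths of 680 and 720 kb. By contrast, 7614 of the 29544 bins called in every group (25.8%) were replicated in at least 80% of window cells in all 8 groups, and 4162 (14.1%) in at most 20%.

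The largest gain of early replication lay on chromosome 18 between 54080001 and 56400000 (mm9). More than 50% of this region was replicated in 6 of 59 d0 cells (10.2%, interval 3.82 to 20.8%) and in 94 of 100 d7 cells (94%, interval 87.4 to 97.8%). On chromosome 10, the region from 91120001 to 92240000 went from 1 of 59 cells (1.69%, 0.0429 to 9.09%) to 78 of 101 (77.2%, 67.8 to 85.0%). It stayed near its d0 share until late: its mean share was 13.2% at d5, 65.3% at d6 and 78.01% at d7. Chromosome 14 from 22960001 to 24640000 moved sooner, with mean shares of 19.5% at d0, 67.4% at d5 and 88.0% at d7. The region on chromosome 7 from 76720001 to 78960000 rose through every sampled day, from 8.25% at d0 to 24.6% at d2, 47.5% at d5 and 75.6% at d7. The other 4 of the 8 largest lay on chromosome 2 (147280001 to 148400000, 21.8% to 83.7%), chromosome 9 (32400001 to 33200000, 12.0% to 73.6%), chromosome 6 (36080001 to 37200000, 13.6% to 74.3%) and chromosome 12 (25920001 to 28960000, 17.3% to 77.1%).

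The losses of early replication reached larger differences, but some of the largest lay beside stretches with too few calls. No d0 share could be taken just left of the chromosome 4, 12 and 2 regions named below. Both flanks had d0 shares in 167 of 181 earlier-to-later and 190 of 190 later-to-earlier regions. Chromosome 4 from 146480001 to 147200000 was replicated over more than 50% of its length in 58 of 59 d0 cells (98.3%, 90.9 to 99.96%) and 7 of 100 d7 cells (7%, 2.86 to 13.9%). Its mean share was 97.9% at d2 and 100% at d3, and then 75.3% at d4, 32.4% at d5 and 12.8% at d6. Chromosome 13 held 2 of the 8 largest losses, separated by less than 2 Mb. In its region from 64640001 to 68480000, the longest at 3840 kb, 58 of 59 d0 cells and 5 of 101 d7 cells (4.95%, 1.63 to 11.2%) were replicated; from 61280001 to 62880000 the numbers were 58 of 59 and 8 of 101. On chromosome 7 from 48320001 to 51120000 all 59 d0 cells were replicated (interval from 93.9%) against 5 of 101 d7 cells, and the mean share had reached 68.5% at d2 and 37.3% at d4. The others were chromosome 12 from 22720001 to 23440000 (84.9% to 2.36%, called in 47 d0 and 75 d7 cells), chromosome 2 from 176800001 to 178240000 (90.7% to 20.96%), chromosome 17 from 21360001 to 23520000 (89.2% to 19.7%) and chromosome 6 from 64560001 to 65520000 (92.8% to 23.7%).

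**Figure D1:**
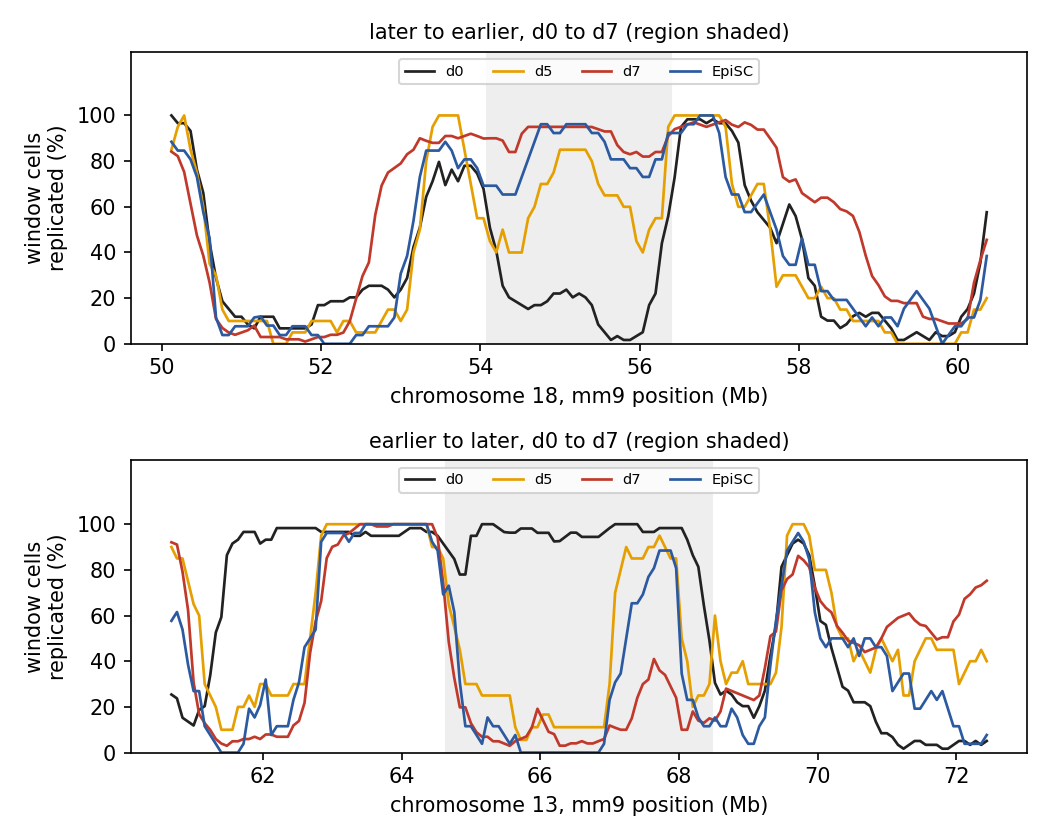
Share of window cells replicated (%, vertical axis) per 80 kb bin along mm9 position in Mb, for d0, d5, d7 and EpiSCs; 1 line per group, with the changed region shaded. In the chromosome 18 region the d0 line lies far below the d7 and EpiSC lines (region means 19.2%, 90.2% and 83.0%), and in the chromosome 13 region it lies above them on average (93.5%, 14.1% and 25.5%).

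Part of the d0 and d7 cells had come from a previous series by the submitters, 50 of 59 at d0 and 35 of 101 at d7. Among previous-series cells alone, 2992 bins were later-to-earlier and 2337 earlier-to-later, including 2224 and 2024 of the bins above. The 8 named gains measured 56.5 to 76.9 points among them, and the 8 named losses measured -90.6 to -69.997 points. With only cells of the present series, 9 of which were at d0, the counts were 3670 and 4479, the named gains measured 23.2 to 67.02 points and the named losses -78.02 to -54.8 points, except the chromosome 12 loss, which had no present-series d0 value. Gains moved by more than 1.5 times on chromosome 2 (69.02 points in previous-series and 23.2 in present-series cells, under the size rule), chromosome 12 (64.5 and 36.6), chromosome 7 (73.3 and 45.2) and chromosome 18 (76.9 and 49.5). Without the present-series cells whose calls did not follow the mean profile, which left 6 cells at d0 and 63 at d7, the named gains measured 42.7 to 72.98 points and the losses -90.4 to -61.4 points. As a yardstick within one day, present-series and previous-series d7 cells differed by 0.3 or more in 52 and 85 bins (r = 0.979 across bins), with 12.2 and 11.8 from counting error. The same comparison at d0 gave 3413 and 3240 bins (r = 0.831) with all 9 present-series cells, against 391.9 and 384.9 from counting error. Without 3 of them whose calls did not follow the mean profile it gave 1643 and 281 bins (r = 0.929), against 693 and 676.

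The time course asked when between d0 and d7 these bins moved. Relative to d0, 456 bins were earlier and 2073 later at d2, 1494 and 2599 at d3, 959 and 2084 at d4, 1307 and 1827 at d5, and 1814 and 2615 at d6. Counting error alone would give 14.6 and 13.9 bins at d2, 184 and 185 at d3, 85.8 and 83.3 at d4, 62.3 and 62.4 at d5, and 58.8 and 61.7 at d6. The observed balance of earlier and later bins depended on the cells' scores. In cells with scores of 45 to 65%, 7 at d3 and 13 at d4, more bins were earlier at d2 to d5. Earlier bins then outnumbered later ones at d4. The bins that end later at d7 fell from 77.7% of cells at d0 to 60.6% at d2, 51.6% at d4 and 34.8% at d6, which was 36.04%, 55.0% and 90.4% of their full change. The bins that end earlier rose from 25.1% to 26.7% at d2, 39.9% at d4, 49.9% at d5 and 60.7% at d6, or 3.52%, 32.5%, 54.6% and 78.5% of the change. With bins chosen on previous-series cells and both ends measured on present-series cells, the later-to-earlier bins lay below their d0 level at d2, d3 and d4, at -76.8%, -63.4% and -19.6% of the change, while earlier-to-later bins stood at 36.8%, 29.5% and 57.2%. The d0 end of those values rests on 9 cells, of which 3 did not follow the mean profile.

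The lead of the earlier-to-later bins depended on the cells' scores, which were lower at d2 than at d0. When d0 and d7 cells were matched in score to the d2 cells, a comparison chosen after seeing the data, earlier-to-later bins had reached 25.1% of their change at d2 and later-to-earlier bins 17.5%. At d3 they stood at 17.5% and 16.97%, at d4 at 44.8% and 46.7%, and at d6 at 83.2% and 87.8%. The bins that passed the size rule at d2 became 777 earlier and 1331 later against matched d0 cells. At d3 and d4, more bins were likewise earlier against matched d0 cells than against all d0 cells. With the midpoint of a logistic fit over all of S phase in place of the window share, the order at d2 turned round, with 31.5% reached by later-to-earlier and 21.8% by earlier-to-later bins. Within d2, cells corrected with different G1 controls (12 and 23 cells) correlated at r = 0.8998 across bins, below the r = 0.920 of all d2 with d0 cells, though small sets lower r by themselves.

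**Figure D2:**
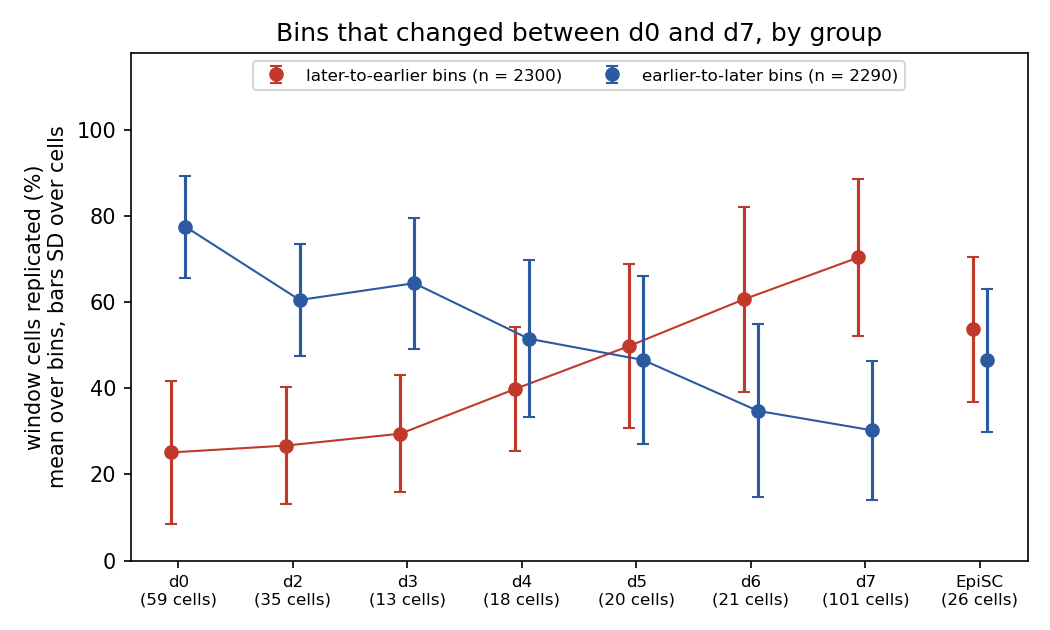
Mean share of window cells replicated (%, vertical axis) over the 2300 later-to-earlier and 2290 earlier-to-later bins at each day and in EpiSCs; bars are SDs over cells. The sets cross between d4 and d5, where later-to-earlier bins went from 39.9% to 49.9% and earlier-to-later bins from 51.6% to 46.6%; d0 and d7 were used to choose the bins.

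Whole profiles were compared by correlation. The correlation with d0 across bins was r = 0.920 at d2, 0.855 at d3, 0.891 at d4, 0.894 at d5, 0.851 at d6 and 0.837 at d7, where bins are not independent replicates. Its fall was not steady, and d0 cells of the previous and present series (50 and 9 cells) correlated at 0.831, or at 0.929 without 3 cells, and the d2 value of 0.920 lay between these. The closest pair of groups was d6 and d7 (r = 0.962), followed by d4 and d5 (0.932) and d2 and d4 (0.930). The d3 profile, from 13 cells, correlated least with d7 (r = 0.744).

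Each cell was placed along this change by an index, the share of its later-to-earlier bins replicated minus the share of its earlier-to-later bins replicated. The median index was -0.56 ± 0.10 (SD over cells) at d0, -0.35 ± 0.089 at d2, -0.34 ± 0.089 at d3, -0.10 ± 0.13 at d4, 0.095 ± 0.21 at d5, 0.38 ± 0.27 at d6 and 0.45 ± 0.20 at d7. EpiSCs had a median of 0.031 ± 0.11. Its bins were chosen on these same d0 and d7 cells, which can push their medians apart and lower the d0 95th percentile used below. The index was also not matched in score. At d0, 5 cells with the same G1 control and a mean score of 68.4% had indices of -0.42 to -0.35. With another control, 33 d0 cells with a mean score of 55.3% had -0.65 to -0.50. Score and control cannot be told apart there, and part of the difference between days may come from either. With bins chosen on previous-series cells alone, the 9 present-series d0 cells had a median of -0.347 and the d2 cells, all of the present series, -0.346. Of those 9 cells, 3 did not follow the mean profile, and their scores spanned 40.2 to 69.8%. At d2, 18 of 35 cells lay at or below the d0 95th percentile of -0.35, all 18 among the 23 cells corrected with one G1 control and none among the 12 corrected with the other. At d3 5 of 13 did (38.5%, 13.9 to 68.4%), and at d4 1 of 18. Later days kept a few such cells: 3 of 20 at d5 (15%, 3.21 to 37.9%), 2 of 21 at d6 (9.52%, 1.17 to 30.4%) and 2 of 101 at d7 (1.98%, 0.241 to 6.97%). None of the 26 EpiSCs did, which allows a share of up to 13.2%.

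**Figure D3:**
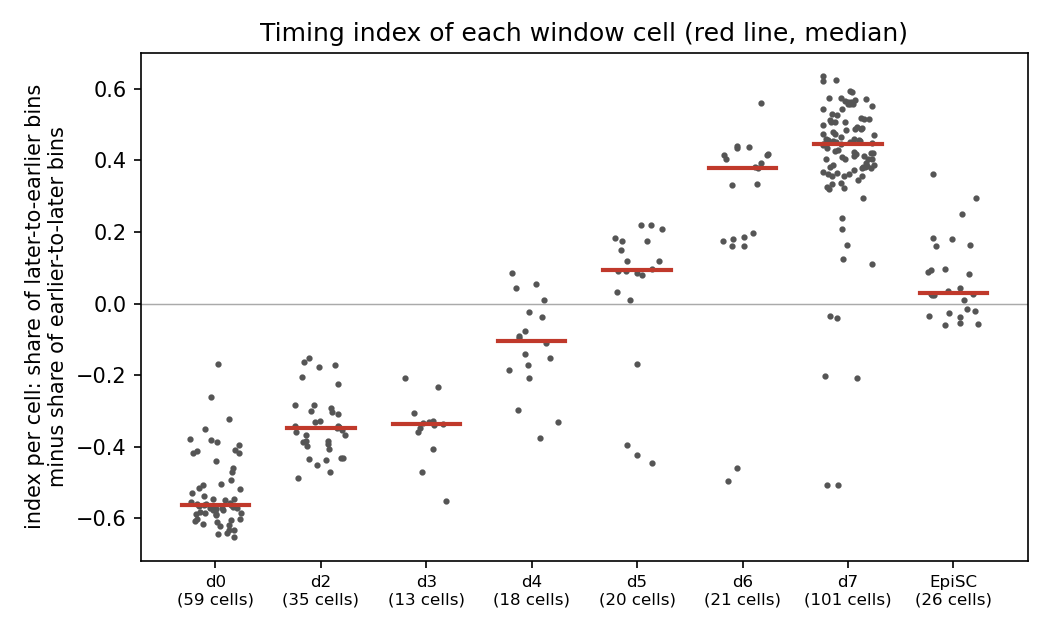
Index of every window cell (dots; vertical axis, difference of shares, no unit) by group, with the median as a red line. Medians go from -0.56 at d0 to 0.45 at d7, and 7 cells of d5 to d7 lie between -0.51 and -0.40.

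EpiSCs, which are grown with activin and FGF, were compared with d0 and d7 to place a stable primed state against the differentiation. They were of another strain (C57BL6) than the CBMS1 cells, so state and strain cannot be told apart. From d0 to EpiSC, 2187 bins were later-to-earlier and 1883 earlier-to-later, with 31.8 and 31.6 from counting error. By the stricter rule of a 30-point shift in the score at which a bin replicates, 642 and 631 bins moved. The largest gains were on chromosome 3 from 148320001 to 149360000 (5 of 58 d0 cells, 8.62%, 2.86 to 18.98%; 22 of 26 EpiSCs, 84.6%, 65.1 to 95.6%), on chromosome 18 within the region above, on chromosome 5 from 98320001 to 99440000 (9.34% to 75.5% mean share) and on chromosome 16 from 57440001 to 58560000 (22.6% to 87.4%). The largest losses were a 2640 kb part of the chromosome 13 region named above, the same chromosome 4 region, chromosome 12 from 22720001 to 23520000, and chromosome 8 from 43760001 to 45040000, where 53 of 59 d0 cells and 0 of 26 EpiSCs were replicated (upper limit 13.2%). In the chromosome 13 part from 64800001 to 67440000 the numbers were 57 of 59 and 0 of 26.

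Changes towards EpiSC and towards d7 shared many bins. Of the 2300 bins later-to-earlier at d7, 1112 (48.3%) were also later-to-earlier in EpiSCs, and 1101 of 2290 earlier-to-later bins (48.1%) were shared. Opposite directions occurred in 7 and 11 bins. Independent lists of these sizes would share 169 and 145 bins, and unchanged groups compared with the same d0 cells shared 0.1 and 0 bins in simulation. With the d0 cells split into sets of 30 and 29, one for each comparison, 1048 and 1047 bins were shared, against 176 and 153 for independent lists. The numbers for independent lists are drawn from all bins and are too low, since bins already early or late at d0 cannot move further that way. EpiSCs stood at 63.1% of the d0-to-d7 change over later-to-earlier bins and at 65.5% over earlier-to-later bins. The 63.1% was lower with bins chosen on previous-series cells and both ends measured on present-series cells. EpiSCs correlated with d5 at r = 0.913, with d6 and d7 at 0.894 each and with d0 at 0.857.

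Direct comparison of EpiSC with d7 gave 1455 bins earlier and 1705 later at d7, with 19 and 17.2 from counting error. By the stricter rule of a 30-point shift in the score at which a bin replicates, 96 and 424 bins moved. Among the bins earlier at d7, chromosome 10 from 70000001 to 70720000 stood out: it was replicated in 8 of 26 EpiSCs (30.8%, 14.3 to 51.8%) and 95 of 101 d7 cells (94.1%, 87.5 to 97.8%), with a mean share of 79.7% at d0. The others were chromosome 13 from 71840001 to 73360000 (16.8% in EpiSCs, 73.9% at d7), chromosome 7 from 78000001 to 79040000 (19.2% and 75.2%) and chromosome 5 from 75840001 to 76400000 (37.9% and 92.9%). Among bins later at d7, chromosome 2 from 54800001 to 55680000 was early only in EpiSCs of all groups, in 22 of 26 cells (84.6%, 65.1 to 95.6%), with mean shares of 24.3% at d0 and 4.59% at d7. Chromosome 6 held 2 regions later at d7 than in EpiSCs, 123520001 to 124240000 (82.9% in EpiSCs, 16.4% at d7) and 128800001 to 129600000 (85.8% and 22.3%); the latter was at 57.6% at d0 and 74.8% at d3. Chromosome 15 from 65280001 to 66560000 (83.7% in EpiSCs) had mean shares of 70.9% at d0, 56.6% at d2 and 73.1% at d5, and then 22.3% at d6.

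Agreement between cells of a group was measured in pairs whose scores differed by at most 5 points. The median share of bins called alike was 85.0% at d0, 83.6% at d2, 80.0% at d3, 83.2% at d4, 84.4% at d5, 83.0% at d6, 82.6% at d7 and 83.3% in EpiSCs. The lowest pair reached 34.5% at d0, 38.2% at d4 and 46.9% at d7, and 74.1% or more in the other groups. The score span over which a bin went from 25 to 75% of cells replicated, fitted over all S-phase cells with scores of 5 to 95%, had a median of 13.4 points at d0, 14.8 at d2, 14.1 at d3 and d4, 13.4 at d5, 12.7 at d6, 16.3 at d7 and 13.4 in EpiSCs. At d7, changed bins had wider spans than other bins of the same timing class, with means of 20.4 against 14.9 points in early bins, 19.3 against 17.9 in middle bins and 19.7 against 16.2 in late bins. Early changed bins were wider in every group, at d0 with means of 15.3 against 13.004 points, and middle ones at d0 had 14.5 against 13.7 points. Late changed bins at d0 were narrower, with 13.9 against 15.5 points. Spans from few cells come out too short: in simulated calls with the 39 d3 cells the fitted span was 0.338 to 0.836 of the true one, against 0.852 to 1.02 with the 189 d7 cells.

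Chromosome X was read per allele in 400 kb windows in cells labelled as carrying 2 X chromosomes, to follow the onset of X inactivation. At d0, the CBA allele was replicated in 43.5% ± 7.04 of windows (SD, 33 cells) and the MsM allele in 44.1% ± 7.10, a difference of -0.577 ± 4.46 points. At d2 the values were 38.3% ± 9.35 and 35.98% ± 9.03 (27 cells). Single cells differed between alleles by -13.1 to 11.1 points at d0 and by -9.54 to 16.3 points at d2. At d7 the active X was replicated in 36.03% ± 8.41 of windows and the inactive X in 5.55% ± 6.52 (36 cells), a difference of 30.5 ± 6.51 points. The cells read per allele were 36 of the 101 window cells at d7, 33 of 59 at d0 and 27 of 35 at d2, and the others may differ. The submitters named the active and inactive X of these d7 cells from replication timing itself, so the direction at d7 follows from that naming. The active X was MsM in 33 cells and CBA in 3. The mean of both alleles minus the autosomal score was -14.1 ± 3.81 points at d0, -15.4 ± 5.02 at d2 and -34.6 ± 5.10 at d7.

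**Figure D4:**
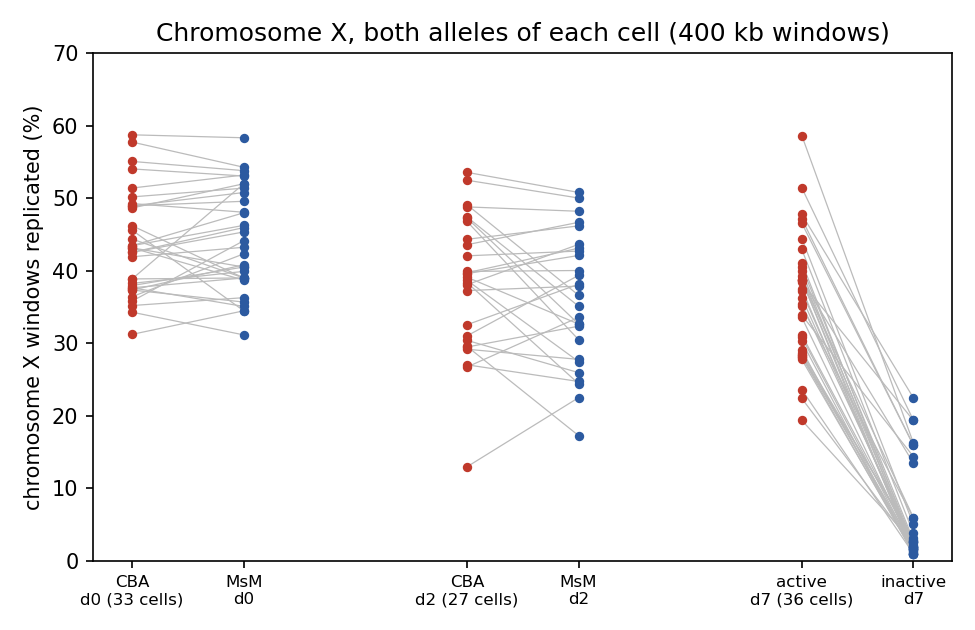
Chromosome X windows replicated (%, vertical axis) on each allele of each cell, as dots joined by a line per cell, at d0, d2 and d7. Alleles overlap at d0 and d2, and at d7 the inactive X lies at 0.935 to 22.4%.

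At d7, 137 of 316 windows were replicated on the active X at least 30 points more often than on the inactive X, and none the other way round. At d0, 8 of 325 windows differed by that much towards CBA and 12 towards MsM. The largest d7 difference was at 45600001 to 46000000, replicated in 36 of 36 active and 1 of 36 inactive chromosomes (2.78%, 0.0703 to 14.5%). Next came 50000001 to 50400000 (35 and 1 of 36), 34400001 to 34800000 (35 and 2 of 36) and 39200001 to 39600000 (33 and 0 of 36). The smallest differences were negative, at -19.4 to -5.56 points, and lay in windows replicated in at most 25% of either chromosome. At 164800001 to 165200000, 2 of 36 active and 9 of 36 inactive chromosomes were replicated; at 164000001 to 164400000 it was 3 and 6, at 116400001 to 116800000 1 and 4, and at 161200001 to 161600000 0 and 2. Timing along the active X at d7 correlated with the d0 mean of both alleles at r = 0.810 over 314 windows, and timing along the inactive X at r = 0.363. Of the 316 windows at d7, 132 were replicated on no inactive X and 49 on no active X. Many windows at the floor lower r by themselves, so the lower value does not show that the d0 order was lost.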

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

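Replication scores of G1 cells were examined for single cells far from the rest in the 5 groups with 4 to 10 such cells, and chance picks out about 1 in 20 groups. At d3, 1 of 6 G1 cells had 7.52% of its bins called replicated, and the next highest had 1.04%. At d4, 1 of 7 G1 cells had a score of 8.99%, and the next highest had 1.54%. No explanation of these values was tested, and neither cell is named in the merged G1 control that corrected the window cells of its day. G1 cells were not among the window cells, and entered the timing comparisons only through the merged controls.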

How the results depend on the processing

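Matching cells in score, leaving out the 7 window cells that stood apart from the mean profile and leaving out the cells that the authors' filters had marked were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because no label pairs cells across groups. Each group was 1 sample, so values between groups carry culture and sorting batches that cannot be separated from the day. The 13 window cells at d3 and the 9 present-series cells at d0 limit what was compared with them, and the number of cells, more than the bins called, set the precision of a share. Of 418 alternative values for 80 results, 320 stayed within their limits (1.5 times for a count), 97 moved further, and 1 turned its sign from a value beyond 10 points, the limit for shares of the change. For the index, the agreement between cells and chromosome X, the limit was the SD over cells or pairs. That limit is wide for a median or mean, so staying within it is weak support. Leaving out the cells that stood apart kept all 59 values within limits, and leaving out the authors' marked cells kept all 51. The same held for Spearman correlations (13 values), cell pairs within 2 points (8), bins called in 80% of cells (2), equal cell numbers at d0 and d7 (2), previous-series cells alone (2) and the chromosome X alternatives that were run. Except where a stricter or looser rule explains a count, the cause was not tested.

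With a difference of 0.2 in place of 0.3, later-to-earlier bins stood at -2.12% of their change at d2. Later-to-earlier bins numbered 1037 at d2, 2679 at d3, 1910 at d4, 2457 at d5, 3119 at d6, 3810 at d7 and 3607 in EpiSCs, each against d0, and 2777 from EpiSC to d7. Earlier-to-later bins numbered 3990, 4531, 3837, 3302, 4308, 3713 and 3195 in the same order and 3227 from EpiSC to d7, and 279 earlier-to-later regions formed at d7. With a difference of 0.4, later-to-earlier bins numbered 189 at d2, 873 at d3, 504 at d4, 685 at d5, 996 at d6, 1344 at d7, 1230 in EpiSCs and 661 from EpiSC to d7. Earlier-to-later bins numbered 973, 1401, 1027, 944, 1508, 1355, 1083 and 867 in that order, and 111 later-to-earlier and 107 earlier-to-later regions formed at d7. With runs of at least 10 bins, 80 later-to-earlier and 75 earlier-to-later regions were left. These changes follow from the looser or stricter rule.

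With a shift of 30 points in the logistic midpoint, later-to-earlier bins numbered 856 at d3, 354 at d4, 330 at d5, 682 at d6, 506 at d7, 642 in EpiSCs and 96 from EpiSC to d7. Earlier-to-later bins numbered 129 at d2, 407 at d3, 338 at d4, 482 at d5, 716 at d6, 791 at d7, 631 in EpiSCs and 424 from EpiSC to d7. By this measure later-to-earlier bins had reached 31.5% of their change at d2, 32.03% at d3, 53.7% at d4, 66.3% at d5 and 95.7% at d6, and earlier-to-later bins 21.8% at d2 and 13.4% at d3. The cause was not tested.

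With scores of 45 to 65%, which left 7 cells at d3, later-to-earlier bins numbered 853 at d2, 2715 at d3, 1808 at d4 and 2107 at d5, and earlier-to-later bins 1304 at d4. Later-to-earlier bins had then reached 14.5% at d2, 21.5% at d3, 46.9% at d4 and 75.8% in EpiSCs, and earlier-to-later bins 17.5% at d3 and 40.8% at d4. With d0 and d7 cells matched in score, the shares reached were 17.5% at d2 and 46.7% at d4 for later-to-earlier bins, and 25.1% at d2, 17.5% at d3 and 44.8% at d4 for earlier-to-later bins. Later-to-earlier bins numbered 777 at d2, 2464 at d3 and 1582 at d4, and earlier-to-later bins 1331 at d2.

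With every group thinned to 13 cells in a single random draw, later-to-earlier bins numbered 690 at d2, 1471 at d4 and 2361 from EpiSC to d7. Earlier-to-later bins numbered 4083 at d2, 4240 at d3, 3298 at d4, 3614 at d5, 4639 at d6, 2956 in EpiSCs and 2855 from EpiSC to d7. Fewer cells spread more, but most of these moves were in the earlier-to-later direction. Whether the number of cells accounts for them was not tested. With present-series cells alone, 3670 bins were later-to-earlier and 4479 earlier-to-later at d7. With bins chosen on previous-series cells and both ends measured on present-series cells, later-to-earlier bins stood at -76.8% of the change at d2, -63.4% at d3 and -19.6% at d4, so the direction turned at all 3 days, and at 23.8% at d5, 66.5% at d6 and 42.3% in EpiSCs, and the d0 median index in present-series cells was -0.347. The d0 end of these values rests on 9 cells, and the cause was not tested.

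Alternatives not run were chromosome X at 80 kb, since the table used holds autosomes only, the gene lists, for want of an annotation of the same build, and the MidS gate at d2, where no cell has that gate. Chromosome X minus autosome in present-series cells gave no value at d0, where at most 1 such cell was in the tables used, and it was measured from the allelic 400 kb tables.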

Other observations

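The tests on previous-series cells alone, on poor calls and on a swap of labels were chosen after their results had been seen, and matching in score and leaving out 7 window cells were alternatives added after seeing the data; each pattern below had been noticed in these data before it was tested.

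Changed regions differed in the timing of their flanks, but the size rule favours such a difference by itself. A bin already early at d0 has little room to gain, and a bin already late has little room to lose. Gains therefore tend to end at early bins and losses at late bins, and no baseline for this was calculated. Of the 190 later-to-earlier regions between d0 and d7, 65 (34.2%) were flanked at d0 by bins replicated in at least 50% of cells on both sides, 89 on one side and 36 on neither. Of the 167 earlier-to-later regions with calls on both flanks, 23 (13.8%) had such flanks on both sides, 92 on one and 52 on neither. Chromosomes contributed unevenly: chromosome 13 had the highest share of changed bins in both directions, with 12.1% later-to-earlier and 13.9% earlier-to-later. On chromosome 17, 11.5% of bins moved later and 3.57% moved earlier. Chromosome 11 had 2.76% moving later, the lowest of the 19, and 7.81% moving earlier, and chromosome 8 had 5.26% and 10.6%.

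On the inactive X at d7, 2 adjacent windows stood apart from the rest, chosen after their values were seen. From 100400001 to 101200000, each of these windows was replicated in 28 of 36 inactive chromosomes (77.8%, exact interval 60.8 to 89.9%), and on the active X in 33 and 30 of 36. The next highest window, 166000001 to 166400000, was replicated in 15 of 36 (41.7%, 25.5 to 59.2%). Of all 36 cells, 8 had more than 10% of inactive X windows replicated, at 13.4 to 22.4%, and their autosomal scores were 59.7 to 68.3%. All of these except the highest were of the MidS gate and the previous series, as were some of the remaining cells. Score, gate and series were not separated. The other 28 cells reached at most 5.92%, with scores of 41.4 to 68.8%.

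Some changes seen at intermediate days were not present at d7. Of 1494 bins earlier at d3 than at d0, 348 were also earlier at d7, and 626 (41.9%) were back within 0.1 of their d0 share. Of 2599 bins later at d3, 541 were also later at d7 and 955 were back. At d6, 1424 of 1814 earlier bins and 1743 of 2615 later bins were shared with d7. These lists share their d0 cells. With d0 cells split between the comparisons, d3 shared 330 of 1548 earlier and 538 of 2827 later bins with d7 (125 and 210.4 for independent lists), and d6 shared 1334 of 1870 and 1616 of 2724 (150.3 and 209 for independent lists). The numbers for independent lists are drawn from all bins and are too low, since bins already early or late at d0 cannot move further that way. The d3 profile rests on 13 cells.

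Bins that moved from earlier to later ran ahead at d2, having reached 36.04% of their change when later-to-earlier bins had reached 3.52%, a gap of 32.5 points. The lower scores of d2 window cells are a candidate explanation, since they lower every share. With d0 and d7 cells matched in score to the d2 cells, the gap was 7.68 points, as that explanation predicts. Window cells that stand apart from the mean profile do not account for it, since the gap without them was 29.6 points. A lead of the losses in the cells themselves stays open. Over the fewer bins chosen by a shift in the logistic midpoint, the order was the other way round (31.5% for later-to-earlier and 21.8% for earlier-to-later bins). Those are not the bins of the gap above.

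The number of state switches along the chromosomes was lower at d7 than at d0. Among adjacent called bins of a cell, a median of 4.49% of pairs changed state at d0, 5.32% at d2, 6.25% at d3, 5.32% at d4, 4.55% at d5, 3.96% at d6, 3.70% at d7 and 4.48% in EpiSCs. The d7 median was 0.823 of the d0 median. Technical explanations were argued against by a ratio of 0.811 in cells with scores of 50 to 60%, 0.817 with runs under 3 bins left out and 0.847 among previous-series cells alone. In sets of 10 or more cells with the same G1 control, medians were 4.62% (33 cells) and 4.22% (18 cells) at d0, and 3.52% (22 cells), 3.62% (63 cells) and 3.79% (11 cells) at d7. Smaller sets lay outside these, at 9.54% (3 cells) and 3.15% (5 cells) at d0 and 5.09% (5 cells) at d7. No control served both days, so the control stays open as a source, and so does read depth; fewer and longer domains at d7 may add to it, as a hypothesis.

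A few cells of d5, d6 and d7 had an index at or below the d0 95th percentile of -0.35: 3 at d5 (-0.44, -0.42 and -0.40), 2 at d6 (-0.50 and -0.46) and 2 at d7 (both -0.51). At d7, 2 further cells (-0.21 and -0.20) lay above that percentile but within the full d0 range, and were not part of what follows. For the 7 cells, poor calls are argued against, since over bins that did not change between d0 and d7 their calls followed the mean profile with areas under the curve of 0.955 or more, above the 5th percentile of 0.924 of all window cells of these days. The highest index of the 59 d0 window cells was -0.17, below the d7 5th percentile of -0.033. This cannot decide on a swap of labels with d0 cells. The d0 cells outside the window had no index, and no comparison was made with the d5 or d6 range. The 2 d7 cells at -0.51 belonged to 1 set of 11 cells corrected with the same G1 control, so a batch of cells stays open. Cells that had kept the timing of the starting state may account for them, as a hypothesis; a wrong label on single cells was not tested.

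Of the 293 window cells, 7 had calls that followed the mean profile poorly, with areas under the curve of 0.248 to 0.681. They were 3 cells of the 75perS gate at d0 (0.428, 0.295 and 0.393), 1 of the 65perS gate at d4 (0.248) and 3 at d7 (0.638, 0.478 and 0.681). The authors' filter on Manhattan distance had marked 3 of them. The 7 G1 cells in no group had scores of 0 to 1.27%, with a median of 0.342%.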
